A study of Mus musculus with 12 samples.

How the data were processed

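RNA of 4 mouse 393P cell lines was measured by 3' tag sequencing (QuantSeq 3' mRNA-Seq, forward kit, paired-end on an Illumina HiSeq, per the labels' protocols). The kit counts tags near the 3' end of each transcript, so a count stands for transcripts and not for transcript length. The 4 lines are a GFP vector control, wild-type Zeb1, and the Zeb1 forms labelled deficient and mimetic, which the series title places in a study of Zeb1 acetylation. Each line has 3 libraries labelled as biological replicates, and n = 3 is used in every group. The series design text instead speaks of 2 replicates per sample, a conflict that the sources used here do not settle and that bears on every n and SD given. Nothing beyond that label says how separate the cultures were, and each Zeb1 form is represented by a single line, so p-values measure the spread between libraries of a line and do not separate the Zeb1 form from other differences between lines.

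The deposited table holds raw counts per gene with no normalisation, 1 column per library. Reads were aligned with STAR to mm10, per the submitters' processing notes; versions, the counting tool and the annotation are not given in the sources used here. The table has 12208 gene rows, and the smallest count of any listed gene in any library is 1. Every listed gene thus has counts in all 12 libraries, and a gene with 0 counts in any library is not analysed here. Several epithelial genes of the fixed lists, including Epcam, Esrp1 and Rab25, are not analysed here either. Changes that end in complete loss or start from 0 counts are thus not covered. Library totals ran from 24.4 to 39 M counts. Gene IDs were matched to GENCODE M21 (GRCm38, the assembly of mm10), where 12195 of the 12208 IDs were found and 11959 had the same symbol; coordinates are from that annotation. Counting strand is not stated, so overlapping and antisense genes, and genes with near-identical copies, are uncertain.

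Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr, which left 12027 tested genes and removed 181. TMM factors were used, a quasi-likelihood model with a coefficient per line was fitted over all 12 libraries so that the lines share an estimate of spread, and 6 pairs of lines were compared. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and "rose" and "fell" refer to such calls. Levels are CPM, counts scaled by TMM-normalised library size, as mean ± SD, n = 3. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic.

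Before the data were examined, 32 gene lists were fixed, of which 30 had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Estimated correlations and fry were run beside it. Also fixed then were the comparisons, the tests and the rule for named genes. The rule takes Zeb1, Cdh1, Vim, Crb3 and Epcam where tested (Epcam was not); up to 4 tested members per described list with the smallest adjusted p; and, among genes with an adjusted p under 0.05, the genes with the largest log2 fold change per direction, 10 in 4 comparisons and 5 in mimetic against WT and deficient against WT. The last group needed a mean of at least 10 CPM in the higher line, no overlap of replicates and an annotated name. Some genes that the rule takes are not reported here. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library size only, no filter, a filter of at least 5 CPM in 3 libraries, fits of only the 2 lines compared, a replicate block, a 2-fold minimum, a prior count of 0.5, and leaving out each library in turn. A fit without the satellite-containing and mitochondrial genes was added after seeing the data.

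The procedure was tested on counts simulated for mimetic against deficient from each gene's mean over all 12 libraries, its estimated dispersion and the real library sizes, with genes changed in the mimetic libraries (11967 genes in that step). Over all expression levels, 83.7% of genes with a 2-fold rise, 68% with a 1.5-fold rise and 57.1% with a 1.25-fold rise were called. Among genes with at least 10 CPM these shares were 100%, 100% and 73.7%, and 0.06% of all unchanged genes were called. The simulation left 11769 of the 11967 genes unchanged, whereas 27.4% of genes were called in the real comparison. Recovery and false calls where many genes change were therefore not tested. A simulated list of 30 genes changed 1.5-fold was called and none (0) of 20 unchanged lists was. Genes were drawn independently of each other there, so lists whose genes vary together were not tested. Replicates differed by more than sampling noise (mean chi-square per gene 2.99 to 23.9), so no library was counted as a copy of another.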

Results

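Gene expression was measured in 393P cells, a mouse lung cancer line that the labels describe as epithelial and non-metastatic, carrying a GFP vector, wild-type Zeb1 (WT), or the Zeb1 forms labelled deficient and mimetic. Zeb1 is a zinc-finger transcription factor that represses epithelial genes and drives the epithelial-mesenchymal transition. The series title concerns acetylation of this protein, and the deficient and mimetic lines are read here as acetylation-deficient and acetylation-mimetic mutants, not as loss of Zeb1. Each line had 3 libraries, with 33.3 to 39 M counts in vector, 28.4 to 35.8 M in WT, 31 to 33 M in deficient and 24.4 to 27.5 M in mimetic. The libraries separated by line, with component 1 (48.5% of the variance) setting vector apart from the Zeb1 lines and component 2 (26.2%) setting WT apart from both mutants. RNA composition also moved with the line. The mitochondrially encoded share of counts was 0.933% ± 0.103 in vector, 0.707% ± 0.0129 in deficient, 0.496% ± 0.0122 in mimetic and 0.412% ± 0.015 in WT (SD, n = 3). The ribosomal protein share was 5.88% ± 0.307, 6.57% ± 0.195, 7.23% ± 0.0733 and 7.74% ± 0.0371 in the same order. Gene models that contain satellite repeats summed to 4097 to 6031 CPM in the vector libraries and 5740 to 16530 in deficient, against 62.6 to 312 in WT and 22.3 to 95.5 in mimetic. Where a count of list members differed when adjusted over the list alone, both are given; elsewhere both were equal.

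**Figure D1:**
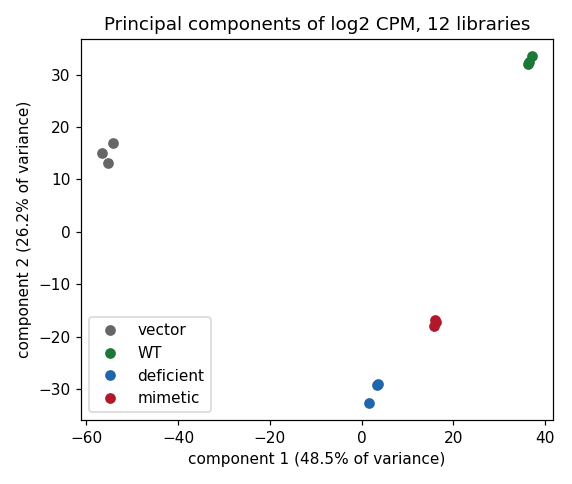
Principal components of log2 CPM for the 12 libraries, component 1 (48.5% of variance) against component 2 (26.2%), coloured by line. The 3 libraries of each line lie together, vector at -54.2 to -56.5 on component 1 and WT at 36.2 to 37.

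Zeb1 RNA (chromosome 18, 5591860 to 5775467, GRCm38) checked only that the Zeb1 lines differ from vector. No mutation was read here, so which line carries which form was not checked. Zeb1 RNA stood at 31.3 ± 2.8 CPM in vector, 244 ± 6.9 in WT, 484 ± 13 in deficient and 228 ± 12 in mimetic (SD, n = 3). The log2 fold changes against vector were 2.97 (SE 0.06, adjusted p = 1.1e-19), 3.95 (SE 0.06, adjusted p = 1.98e-21) and 2.87 (SE 0.06, adjusted p = 3.4e-19), from edgeR's quasi-likelihood test. The deficient line had 1.98 times the WT level (adjusted p = 2.07e-12), while mimetic and WT differed by -0.10 on the log2 scale (SE 0.05, adjusted p = 0.14). These counts mix the resident gene with whatever part of the introduced transcript carries a countable Zeb1 3' end, and they measure RNA and not protein. The median log2 fold change of all chromosome 18 genes of at least 5 CPM was -0.25, -0.24 and -0.26 in the 3 Zeb1 lines against vector.

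**Figure D2:**
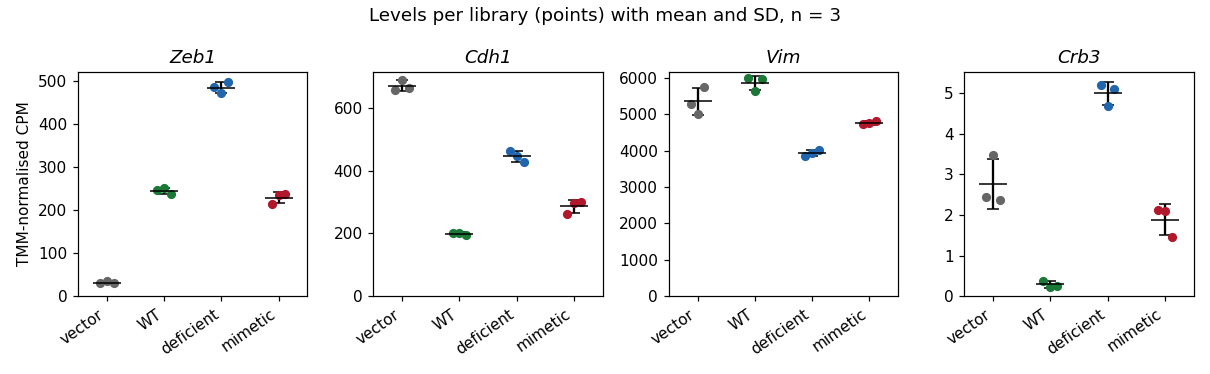
TMM-normalised CPM of Zeb1, Cdh1, Vim and Crb3 in each library (points) with the line's mean and SD (n = 3), on axes that start at 0. Zeb1 was highest in deficient (484 CPM), whereas Cdh1 was lowest in WT (198 CPM).

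The comparison of WT with vector asks what wild-type Zeb1 changed. Epithelial genes fell widely. E-cadherin (Cdh1, chromosome 8, 106603351 to 106670246) went from 670 ± 18 to 198 ± 4.4 CPM, 3.38-fold lower. The keratin Krt7 fell from 866 ± 52 to 58.8 ± 2.3 CPM, the desmosome linker Dsp from 111 ± 5.8 to 3.98 ± 0.26, and the protease inhibitor Spint2 from 144 ± 8.7 to 17 ± 1.3. Of the 45 epithelial genes listed, 31 were tested; 26 fell and 2 rose (26 and 2 adjusted over the list alone), with a median log2 fold change of -1.62 and camera adjusted p = 6.6e-11, which was 0.032 as the adjusted p with an estimated correlation. Genes known as direct ZEB1 targets overlap that list. Of 10 tested, 6 fell, among them the polarity genes Patj (3.9-fold) and Pard6b (4.18-fold), and 2 rose (camera adjusted p = 0.018; adjusted p = 0.11 with an estimated correlation).

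Mesenchymal genes moved less uniformly in WT. Of 30 tested, 18 rose and 3 fell (18 and 3 adjusted over the list alone), with a median of 0.21 and camera adjusted p = 0.0029 (adjusted p = 0.077 with an estimated correlation). Wnt5a, a non-canonical WNT ligand, rose from 0.38 ± 0.069 to 24.2 ± 0.56 CPM and the matrix protein Sparc 2.1-fold. The adhesion molecule Ncam1 went the other way, 23.6-fold lower. Vimentin (Vim, chromosome 2, 13573927 to 13582826) was 5870 ± 190 CPM against 5360 ± 370, a log2 fold change of 0.13 (adjusted p = 0.0151) that was small. The call for Vim in WT vs vector was lost without vector replicate 2 (adjusted p = 0.0941), without WT replicate 1 (adjusted p = 0.0541) or without WT replicate 3 (adjusted p = 0.053), edgeR's quasi-likelihood test.

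Other groups fell in WT as well. Of 21 tested sterol synthesis and uptake genes, 16 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 0.001, adjusted p = 0.046 with an estimated correlation), including Hmgcs1, 2.03-fold. Integrin and laminin genes fell in 19 of 30 and rose in 6 (camera adjusted p = 0.007; adjusted p = 0.3 with an estimated correlation), including the laminin chain Lamb3, 5.93-fold. Interferon-stimulated genes fell in 12 of 18 and rose in 1 (13 and 1 adjusted over the list alone), and inflammatory genes fell in 17 of 22 and rose in 3 (17 and 4 adjusted over the list alone; both camera adjusted p = 0.0048; adjusted p = 0.073 with an estimated correlation). S, G2 and M phase genes rose in 25 of 42 and fell in 10 (camera adjusted p = 0.0048; adjusted p = 0.32 with an estimated correlation). Heat shock genes rose in 10 of 15 and fell in 1 (10 and 2 adjusted over the list alone; camera adjusted p = 0.02, adjusted p = 0.26 with an estimated correlation). Ribosomal protein genes rose in 51 of 59 and fell in 1 (camera adjusted p = 3.7e-10; adjusted p = 0.37 with an estimated correlation), and mitochondrially encoded genes fell in 11 of 12 (camera adjusted p = 0.00081; adjusted p = 0.3 with an estimated correlation). Among single genes, the lactate transporter Slc16a3 rose from 2.76 ± 0.36 to 69.5 ± 0.64 CPM and Ddah1 from 2.79 ± 0.37 to 68.5 ± 1.4. The largest falls included Lgals4 (135 ± 7 to 1.47 ± 0.14 CPM) and the selenium carrier Selenop (175 ± 7.6 to 2.32 ± 0.14).

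In all, 7769 of 12027 genes were called between WT and vector, 3725 higher and 4044 lower, of which 583 and 903 changed at least 2-fold. With scaling by library size only, 3892 were higher and 3873 lower. Most called changes were therefore small, and 11 of 30 lists were called, of which 2 held with an estimated correlation.

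The comparison of deficient with vector asks what the acetylation-deficient form changed. Epithelial genes split. Cdh1 fell to 445 ± 17 CPM, 1.51-fold lower than vector, Spint2 1.75-fold and the tetraspanin Tspan1 2.34-fold. The claudin Cldn3 rose from 16.8 ± 1.1 to 44.1 ± 4.4 CPM and Crb3, a polarity gene (chromosome 17, 57059105 to 57065918), from 2.77 ± 0.61 to 5 ± 0.28. In total 15 of 31 epithelial genes fell and 10 rose (15 and 10 adjusted over the list alone), with a median of -0.24 and camera adjusted p = 0.28. Of the 10 ZEB1 target genes tested, 3 fell and 4 rose (camera adjusted p = 0.82). Mesenchymal genes rose in 18 of 30 and fell in 5 (18 and 5 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.16 with an estimated correlation), although Vim fell 1.36-fold to 3940 ± 80 CPM.

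Collagen and crosslinking genes rose in 13 of 25 tested and fell in 3 (camera adjusted p = 0.012; adjusted p = 0.16 with an estimated correlation), with Col6a1 13.3-fold and Col5a1 3.41-fold higher. Genes of the TGF-beta and BMP response rose in 12 of 22 and fell in 4 (camera adjusted p = 0.014; adjusted p = 0.16 with an estimated correlation). Immediate early genes rose in 13 of 20 and fell in 3 (13 and 4 adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.29 with an estimated correlation), including Atf3, 4.61-fold, and Dusp1, 5.12-fold. Fatty acid synthesis genes fell in 11 of 13 and rose in 1 (camera adjusted p = 0.014; adjusted p = 0.16 with an estimated correlation). NRF2 targets fell in 12 of 20 and rose in 4 (camera adjusted p = 0.046; adjusted p = 0.5 with an estimated correlation), and mitochondrially encoded genes fell in 10 of 12 (camera adjusted p = 0.014; adjusted p = 0.5 with an estimated correlation). The phosphatase Ptpn13 rose from 2.24 ± 0.54 to 175 ± 1.4 CPM, and Selenop fell to 1.78 ± 0.38 CPM. A total of 7001 genes were called, 3421 higher and 3580 lower, with 669 and 358 of them at least 2-fold. With scaling by library size only, the split was 3928 higher and 3149 lower. No list (0 of the 7 called) held with an estimated correlation.

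The comparison of mimetic with vector asks the same of the acetylation-mimetic form. Epithelial genes fell again. Cdh1 was 287 ± 21 CPM, 2.34-fold below vector, Krt7 337 ± 11, 2.57-fold, Spint2 42.3 ± 0.46, 3.41-fold, and Tspan1 7.46 ± 1.1, 7.4-fold. Of 31 tested, 24 fell and 4 rose (25 and 4 adjusted over the list alone; median -0.84, camera adjusted p = 6.2e-07, adjusted p = 0.069 with an estimated correlation). Mesenchymal genes rose in 16 of 30 and fell in 5 (19 and 6 adjusted over the list alone; camera adjusted p = 0.0026, adjusted p = 0.079 with an estimated correlation), with Sparc 2-fold and Timp1, an inhibitor of metalloproteinases, 1.95-fold higher. Vim was 4760 ± 47 CPM, 1.12-fold lower (adjusted p = 0.0032). Crb3 was called lower at 1.89 ± 0.38 CPM (adjusted p = 0.034, edgeR's quasi-likelihood test). The call for Crb3 in mimetic vs vector was lost without vector replicate 2 (adjusted p = 0.197), without mimetic replicate 3 (adjusted p = 0.166) and with limma-voom (adjusted p = 0.0552).

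Sterol genes fell in 19 of 21 and rose in 1 in mimetic (19 and 1 adjusted over the list alone; median -0.69, camera adjusted p = 1.5e-07, adjusted p = 0.0062 with an estimated correlation), with Hmgcs1 2.26-fold and the cyclase Lss 2.01-fold lower. TGF-beta and BMP response genes rose in 13 of 22 and fell in 3 (camera adjusted p = 0.0048; adjusted p = 0.071 with an estimated correlation), including the receptor Tgfbr1, 1.98-fold, and Id2, 2.59-fold. Fatty acid synthesis genes fell in 11 of 13 and rose in 2 (camera adjusted p = 0.0018; adjusted p = 0.079 with an estimated correlation). Ribosomal protein genes rose in 41 of 59 and fell in 3 (42 and 3 adjusted over the list alone; camera adjusted p = 1.4e-05, adjusted p = 0.52 with an estimated correlation), and mitochondrially encoded genes fell in 10 of 12 (camera adjusted p = 0.00089; adjusted p = 0.36 with an estimated correlation). Timp3 rose from 0.2 ± 0.095 to 38.4 ± 2.1 CPM and Ptpn13 to 131 ± 6.2 CPM, while villin (Vil1) fell from 32.8 ± 2.2 to 1.59 ± 0.51 CPM. In total 7158 genes were called, 3438 higher and 3720 lower, with 658 and 468 at least 2-fold. With scaling by library size only, the split turned to 4334 higher and 3004 lower. Of the 7 lists called, 1 held with an estimated correlation.

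**Figure D3:**
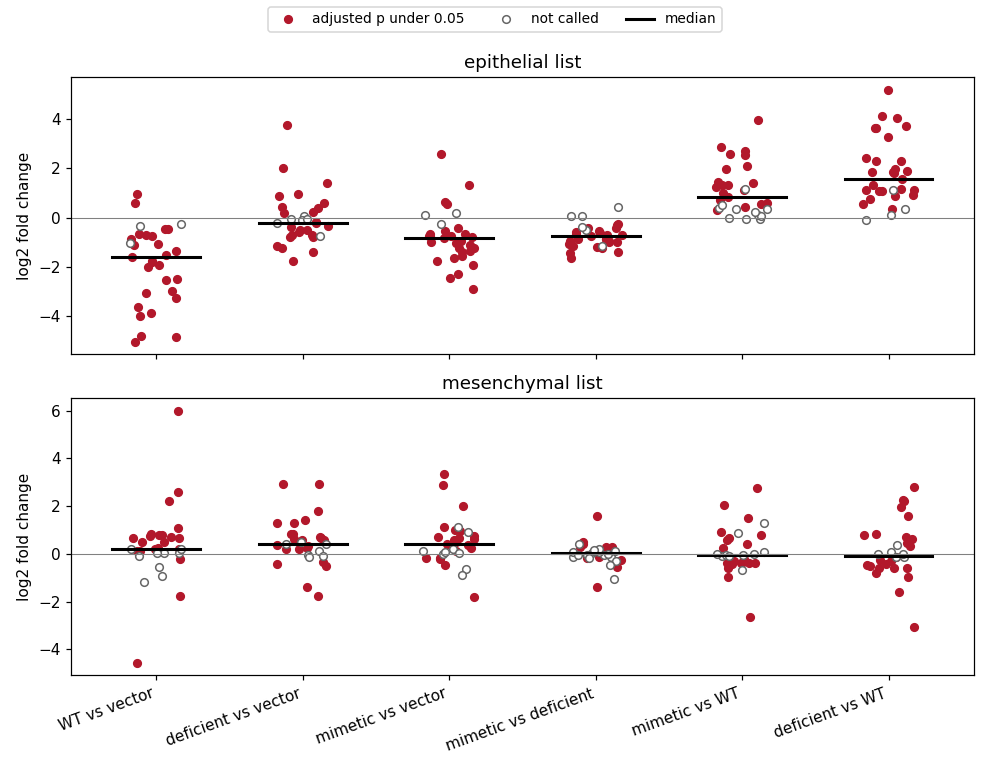
Log2 fold changes of the tested members of the epithelial list (31 genes) and the mesenchymal list (30 genes) in the 6 comparisons; filled points passed an adjusted p of 0.05 and bars are medians. The epithelial median was -1.62 in WT, -0.24 in deficient and -0.84 in mimetic against vector.

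The comparison of mimetic with deficient sets the 2 mutants side by side. No epithelial gene rose (0 of 31) and 25 fell in mimetic relative to deficient (27 fell adjusted over the list alone; median -0.74, camera adjusted p = 1.7e-16, adjusted p = 0.0042 with an estimated correlation). Cdh1 was 1.55-fold lower, the claudin Cldn6 308 ± 9.5 against 613 ± 5.8 CPM, Krt7 337 ± 11 against 762 ± 29 and Dsp 61.7 ± 2 against 144 ± 3.6. ZEB1 target genes fell in 7 of 10 and rose in 1 (camera adjusted p = 0.00096, adjusted p = 0.032 with an estimated correlation). The mesenchymal list was not called, with 7 genes higher and 5 lower of 30 (9 and 6 adjusted over the list alone; camera adjusted p = 0.26). Its median was 0.02, its mean -0.01 and the test's direction upward. Within it the calcium-binding protein S100a4 was 3.04-fold and Vim 1.21-fold higher in mimetic.

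Sterol genes were lower in mimetic than in deficient for 19 of 21 and higher for none (0), with Cyp51 and Msmo1 both 1.59-fold lower (camera adjusted p = 1.3e-14, adjusted p = 0.00064 with an estimated correlation). Hypoxia and glycolysis genes were lower for 21 of 25 and higher for 1 (camera adjusted p = 1.3e-10, adjusted p = 0.032 with an estimated correlation), and inflammatory genes lower for 9 of 22 and higher for 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.00096, adjusted p = 0.032 with an estimated correlation). The cytokine Csf2 (chromosome 11, 54247271 to 54249667) was 3.67 ± 0.33 against 21.9 ± 1.3 CPM. S, G2 and M phase genes were higher for 20 of 42 and lower for 1, with a median of 0.13 (25 and 1 adjusted over the list alone; camera adjusted p = 4.1e-08, adjusted p = 0.067 with an estimated correlation). Integrin and laminin genes were lower for 17 of 30 and higher for 2 (18 and 2 adjusted over the list alone; camera adjusted p = 0.00042, adjusted p = 0.12 with an estimated correlation). Ribosomal protein genes were higher for 22 of 59 and lower for 0 (26 and 0 adjusted over the list alone; camera adjusted p = 3.7e-06, adjusted p = 0.38 with an estimated correlation). Mitochondrially encoded genes were lower for 7 of 12 (camera adjusted p = 0.0079; adjusted p = 0.36 with an estimated correlation). Of subunits of the NuRD complex, a chromatin remodeller and deacetylase named in the series title, 3 of 15 were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.22). In total 3299 genes were called, 1510 higher and 1789 lower, and 120 and 196 changed at least 2-fold. Scaling by library size only gave 1982 higher and 1509 lower. Camera called 19 lists, of which 5 held with an estimated correlation.

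Each mutant was also compared with WT, which asks where a mutant departed from the wild-type form. Epithelial genes were higher in mimetic than in WT for 20 of 31 and lower for none (0; 21 and 0 adjusted over the list alone; median 0.85, camera adjusted p = 4.1e-10, adjusted p = 0.019 with an estimated correlation). Dsp was 61.7 ± 2 against 3.98 ± 0.26 CPM and Krt7 5.73-fold higher. In deficient 27 of 31 were higher than in WT and none (0) lower (27 and 0 adjusted over the list alone; median 1.56, camera adjusted p = 1.1e-15, adjusted p = 0.0099 with an estimated correlation), with Krt7 13-fold and Dsp 36.1-fold higher. Airway cell markers were higher than in WT for 5 of 6 in mimetic (median 1.92, camera adjusted p = 0.0035, adjusted p = 0.058 with an estimated correlation) and for 4 in deficient (median 1.52, camera adjusted p = 0.043, adjusted p = 0.14 with an estimated correlation), and lower for 0 in both. Mesenchymal genes were higher for 9 and lower for 11 of 30 in mimetic (9 and 11 adjusted over the list alone; camera adjusted p = 0.36) and higher for 11 and lower for 13 in deficient (11 and 14 adjusted over the list alone; camera adjusted p = 0.25). The medians were -0.05 and -0.07, the means 0.14 and 0.15, and the test's direction downward in both. Wnt5a (chromosome 14, 28504750 to 28527448) was 24.2 ± 0.56 CPM in WT, 3.84 ± 0.71 in mimetic and 2.88 ± 0.38 in deficient, while the median of all chromosome 14 genes was 0.27 and 0.28 higher on the log2 scale in mimetic and deficient than in WT. The C2-domain gene Mctp1 was likewise lower in both mutants, 15.5 ± 0.32 and 8.33 ± 0.98 against 91.4 ± 3.9 CPM. Of NuRD subunits, 1 was higher and 9 of 15 lower in mimetic than in WT (camera adjusted p = 0.058), and 6 were lower in deficient than in WT (camera adjusted p = 0.021, adjusted p = 0.09 with an estimated correlation). Sterol genes were lower in mimetic than in WT for 16 of 21 and higher for 2 (camera adjusted p = 0.00026, adjusted p = 0.019 with an estimated correlation), and higher in deficient than in WT for 14 and lower for 1 (camera adjusted p = 0.00086, adjusted p = 0.036 with an estimated correlation). Inflammatory genes were higher in deficient than in WT for 15 of 22 and lower for 2 (camera adjusted p = 0.00013, adjusted p = 0.022 with an estimated correlation), and ZEB1 target genes for 7 and 1 of 10 (camera adjusted p = 0.00086, adjusted p = 0.036 with an estimated correlation). In mimetic the counts against WT were 12 and 2 for inflammatory genes (13 and 2 adjusted over the list alone, camera adjusted p = 0.0092, adjusted p = 0.063 with an estimated correlation). For ZEB1 target genes they were 5 and 1 (camera adjusted p = 0.0066, adjusted p = 0.063 with an estimated correlation). TGF-beta and BMP response genes were higher in mimetic than in WT for 14 of 22 and lower for 2 (16 and 2 adjusted over the list alone, camera adjusted p = 0.00025, adjusted p = 0.019 with an estimated correlation). In deficient they were likewise higher than in WT for 14 and lower for 3 (camera adjusted p = 0.0069, adjusted p = 0.066 with an estimated correlation). Ribosomal protein genes were lower than in WT for 36 of 59 and higher for 2 in mimetic (camera adjusted p = 7.5e-05; adjusted p = 0.48 with an estimated correlation). In deficient they were lower for 49 and higher for 1 (50 and 1 adjusted over the list alone; camera adjusted p = 4e-10, adjusted p = 0.25 with an estimated correlation). Mitochondrially encoded genes were higher in deficient than in WT for 8 of 12 (9 adjusted over the list alone; camera adjusted p = 0.0093, adjusted p = 0.31 with an estimated correlation). In mimetic 2 were higher (1 adjusted over the list alone; camera adjusted p = 0.34). With an estimated correlation, 3 of 13 called lists held in mimetic against WT and 4 of 19 in deficient against WT. Called genes numbered 5398 in mimetic against WT (2780 higher, 2618 lower; 3506 and 1980 by library size only) and 6470 in deficient against WT (3311 higher, 3159 lower; 3597 and 2793 by library size only). Of these, 576 higher and 99 lower in mimetic and 875 higher and 181 lower in deficient differed from WT at least 2-fold.

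Fold changes against vector were alike across genes in the 3 Zeb1 lines, with Pearson r of 0.661 between WT and deficient, 0.768 between WT and mimetic and 0.85 between deficient and mimetic. Genes are not independent replicates, and the comparisons share the vector libraries. Simulations without effects, in which all 12 libraries were redrawn, vector included, gave r of 0.493, 0.484 and 0.484. The covariances were 0.429, 0.529 and 0.475, each 0.013 in the simulation, a difference of 0.416, 0.516 and 0.462. The simulations held only the estimated spread between libraries. They called on average 0.05 genes higher in both lines of each pair, and 0.05 or 0 lower in both. With no effect simulated and the model's own spread, almost no calls could arise, so these counts do not weigh the source of the overlap given next. The control libraries cannot be split into parts of at least 2, so what the shared vector line adds was not tested with real libraries. Genes called higher in both numbered 2267, 2475 and 2616, against 1060, 1065 and 978 for independent lists, and genes called lower in both 2485, 2828 and 2809, against 1204, 1251 and 1107. The values for independent lists do not allow for the shared vector line.

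Genes that rose at least 2-fold in WT (583) were called higher in deficient for 85.1% and in mimetic for 89.5%, with a median of 1.65 in WT, 1.43 in deficient and 1.59 in mimetic. Of the 903 genes that fell at least 2-fold in WT, 56.3% were called lower in deficient and 70% in mimetic, with a median of -1.64 in WT, -0.53 in deficient and -0.89 in mimetic. The genes were selected on WT, which favours larger changes there. With genes selected on the mean of the 3 lines instead (598 rose, 497 fell), the ratio of the deficient to the WT mean log2 fold change was 1.13 for genes that rose and 0.51 for genes that fell, and that of mimetic to WT was 1.18 and 0.65. Of the 3299 genes that differed between the mutants, WT lay between both for 34.4%, beyond mimetic for 47.5% and beyond deficient for 18.1%. These classes compare the mean CPM of each line, without a test of WT against either mutant.

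**Figure D4:**
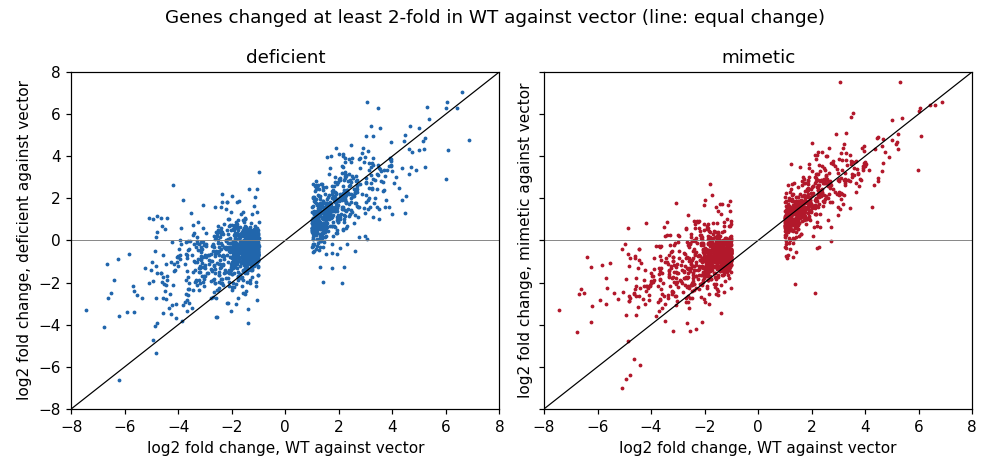
Log2 fold change against vector in deficient (left) and mimetic (right) plotted against that in WT, for the genes changed at least 2-fold in WT (583 higher, 903 lower); the line marks equal change. Genes that fell in WT lie mostly above the line, with medians of -0.53 in deficient and -0.89 in mimetic against -1.64 in WT.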

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

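The test of Zeb1 RNA amount and the count of epithelial genes above the vector level were chosen after the result was seen, and the test of the 4-fold genes before. Effects against vector differed between the Zeb1 lines for 3299 genes (mimetic against deficient), 5398 (mimetic against WT) and 6470 (deficient against WT). The median epithelial log2 difference was -0.74, 0.85 and 1.56 in the same order. Of the 73 genes that the naming rule takes outside the lists, 15 were called in opposite directions against vector in a pair of Zeb1 lines and differed between those lines (63 of 333 with list members counted), by edgeR's quasi-likelihood test. The rule takes the largest differences between Zeb1 lines, which favours such genes. Of all 12027 genes, 546 were called in opposite directions in WT and deficient, 310 in WT and mimetic and 140 in deficient and mimetic. Those 3 counts do not ask for a called difference between the lines. Crb3 was lower in WT and higher in deficient, a log2 difference of 4.13 (adjusted p = 1.13e-10), and mimetic minus deficient was -1.41 (adjusted p = 3.05e-05). Its WT level was 0.286 CPM, a level with few counts, and the call for Crb3 in mimetic vs vector was lost without vector replicate 2 (adjusted p = 0.197), without mimetic replicate 3 (adjusted p = 0.166) and with limma-voom (adjusted p = 0.0552). Vim was higher in WT and lower in both mutants, with differences of -0.58 for deficient minus WT (adjusted p = 1.58e-09) and -0.30 for mimetic minus WT (adjusted p = 1.9e-05). The call for Vim in WT vs vector was lost without vector replicate 2 (adjusted p = 0.0941), WT replicate 1 (adjusted p = 0.0541) or WT replicate 3 (adjusted p = 0.053).

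Other genes lower in WT and mimetic but higher in deficient than in vector were Dsp, Lamb3, Myo5b and Wnt7a, with deficient minus WT at 5.17, 2.84, 1.11 and 4 and mimetic minus deficient at -1.22, -1.58, -1.41 and -1.99 on the log2 scale. Fgfbp1 was lower in WT and higher in both mutants (4.01 for deficient minus WT, 2.62 for mimetic minus WT). Mctp1, Mdga1 and Rab6b were higher in WT and lower in both mutants, with deficient minus WT at -3.45, -4.15 and -3.37 and mimetic minus WT at -2.56, -4.61 and -1.94. Cp, Ildr2, Lbp and Scara5 were lower in WT and deficient but higher in mimetic, with mimetic minus WT at 1.07, 5.45, 1.31 and 1.85 and mimetic minus deficient at 1.60, 1.06, 2.10 and 2.03. Clca3a1 was higher in WT and mimetic and lower in deficient (-2.60 for deficient minus WT, 1.63 for mimetic minus deficient). The adjusted p of these differences was at most 1.58e-05, that of Ildr2.

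Epithelial genes fell least in the deficient line although it had the most Zeb1 RNA. If the amount of Zeb1 RNA alone set the fall, deficient would be lower than mimetic, but 25 epithelial genes were called higher in deficient and 0 lower by edgeR; this count restates the pattern and is no further evidence for it. Vector-like cells within the deficient culture would place each gene between vector and WT. Of 182 genes changed at least 4-fold in WT, 4.4% lay beyond WT in deficient, but selection on WT favours a low share. The median fraction of the way from vector to WT was 0.55 (95% bootstrap interval 0.45 to 0.76) for genes that rose. For those that fell it was 0.68 (0.59 to 0.74), and the intervals overlap, as a mixture would give. These fractions are of mean CPM and cannot be set beside the ratios of log2 fold changes given above. But 7 of the 26 epithelial genes called lower in WT were called higher in deficient than in vector (Cldn3, Cldn6, Crb3, Dsp, Evpl, F11r and Pkp3). A mixture of vector-like and WT-like cells alone forbids this. Of all 12027 genes, 3421 were called higher in deficient than in vector. Vector-like cells beside other differences of the line are therefore not excluded. The mutation, the protein level and other differences of this single line stay open, as untested.

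The 10 ways to split 6 libraries into 2 groups of 3 are too few for a share under 0.05. In fits of only the 2 lines compared, the real split (1 of 10 in each comparison) called 7647 genes for WT against vector, 6501 for deficient against vector, 6851 for mimetic against vector, 3259 for mimetic against deficient, 6081 for mimetic against WT and 6719 for deficient against WT, and the highest of the other splits called 0.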

How the results depend on the processing

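Alternatives were fixed before the data were examined, except the fit without satellite-containing and mitochondrial genes. The 6 counts of called genes stayed within 1.5 times their value in 90 of 96 alternatives; the others are those with a 2-fold minimum, which counts fewer genes by construction: 1486, 1027 and 1126 against vector in WT, deficient and mimetic, 316 in mimetic against deficient, 675 in mimetic against WT and 1056 in deficient against WT. Leaving out 1 library in turn gave 7209 to 7838, 6383 to 6925, 6554 to 7191, 2576 to 2972, 4670 to 4817 and 5794 to 6097 in the same order. The replicate numbers did not pair the libraries (same-number correlations -0.085 to 0.132, 5 of 12 libraries matching best to their own number), and with the replicate block the counts were 7852, 7080, 7250, 3378, 5514 and 6573; the block ended the list calls of NRF2 targets in deficient against vector (adjusted p = 0.053) and of heat shock genes in deficient against WT (adjusted p = 0.054) and changed no other list call. With an estimated correlation, the mesenchymal list had an adjusted p of 0.077 in WT, 0.16 in deficient and 0.079 in mimetic against vector, and the epithelial list 0.069 in mimetic against vector. With fry, which tests direction within a list and not against other genes, the epithelial list was called in deficient against vector (0.002) and the mesenchymal list in mimetic against deficient (0.0019) and deficient against WT (7.7e-05); the stricter filter also called the last (0.041). Fry turned the direction of the TGF-beta list in WT against vector (0.00077), antigen presentation in deficient against vector (0.01) and airway markers in mimetic against deficient (0.011). The cause of these changes was not tested. Correlations of fold changes were 0.718, 0.817 and 0.867 under the stricter filter, which leaves fewer genes with low counts, and 0.775 for WT and mimetic from mean log2 CPM with a prior count of 2. Over the named genes, 7920 of 7980 alternatives kept the side of the threshold, 55 lost the call and 5 gained it. Most named genes were chosen for a small adjusted p or a large fold change in these data, which favours stable calls. Their share thus does not extend to all called genes. Over lists, 1956 of 2148 alternatives kept the side of the threshold, 79 lost the call and 110 gained it. Of the 79, 61 were lost in the setting with an estimated correlation. That setting left 2 of 11, 0 of 7, 1 of 7, 5 of 19, 3 of 13 and 4 of 19 called lists in the order above. In WT against vector, the estimate was below the preset 0.01 for the inflammatory list (-0.025) and the ZEB1 targets (-0.00061), which lost the call too. A higher correlation between genes does not account for those losses, and their cause was not tested. A call lost in this setting, in any comparison, is thus not by itself a sign of correlated genes. Of the 110, 82 came from fry, which tests another hypothesis. In the simulation of mimetic against deficient, 83.7% of genes raised 2-fold were called over all levels and 100% of those with at least 10 CPM. The calls missed there were thus among genes with low counts. Far fewer genes changed in the simulation than were called in the data, and depth itself was not varied.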

Other observations

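The tests of satellite counts and of chance placement and the count of chromosomes with either part shifted were chosen after the results were seen; those of the parts of a chromosome and of GC content and length were written before. Some genes stood apart in a single line by over 8-fold in mean CPM (0.1 added), a description made after the values were seen. In WT 17 genes were lower than in the other 3 lines, among them Dsp, the proteoglycan Vcan, Lgals4 and the receptor Igf2r, and 0 were higher. In vector 34 were lower, including Tgfbi, Ptpn13, Timp3, Fgfr1 and Gdnf, and 9 higher, including Vil1, Ddr2 and Selenop. No gene (0) stood apart so in deficient or in mimetic.

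Lists less fully described in the report are given for mimetic against deficient, with camera. Immediate early genes were lower for 11 of 20 and higher for 3 (11 and 4 adjusted over the list alone; adjusted p = 0.008, adjusted p = 0.18 with an estimated correlation). Fatty acid synthesis genes were lower for 8 of 13 and higher for 1 (9 and 2 adjusted over the list alone; adjusted p = 0.0086, adjusted p = 0.1 with an estimated correlation). Interferon-stimulated genes were lower for 6 of 18 and higher for 1 (7 and 1 adjusted over the list alone; adjusted p = 0.027, adjusted p = 0.1 with an estimated correlation). Unfolded protein and integrated stress genes were lower for 16 of 29 and higher for 3 (16 and 4 adjusted over the list alone; adjusted p = 0.0037, adjusted p = 0.2 with an estimated correlation). NRF2 targets were higher for 9 of 20 and lower for 2 (11 and 2 adjusted over the list alone; adjusted p = 0.0037, adjusted p = 0.2 with an estimated correlation). Targets of p53 and cell cycle inhibitors were lower for 7 of 20 (8 adjusted over the list alone; adjusted p = 0.008, adjusted p = 0.1 with an estimated correlation). RAS-MAPK output genes were lower for 11 of 24 and higher for 5 (12 and 5 adjusted over the list alone; adjusted p = 0.0071, adjusted p = 0.051 with an estimated correlation). WNT, NOTCH and YAP genes were lower for 7 of 21 and higher for 1 (8 and 3 adjusted over the list alone; adjusted p = 0.019, adjusted p = 0.28 with an estimated correlation). Antigen presentation genes were lower for 5 of 14 (adjusted p = 0.027, adjusted p = 0.1 with an estimated correlation), and alveolar type II genes higher for 4 of 12 (adjusted p = 0.027, adjusted p = 0.38 with an estimated correlation).

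Besides the mesenchymal and NuRD lists, lists without a call in mimetic against deficient were collagen and crosslinking genes (6 higher and 9 lower of 25, adjusted p = 0.22), TGF-beta and BMP response genes (8 and 6 of 22, 8 and 7 adjusted over the list alone, adjusted p = 0.38), heat shock (4 of 15 higher, adjusted p = 0.19), acetyltransferases and deacetylases (4 higher and 3 lower of 23, 6 and 3 adjusted over the list alone, adjusted p = 0.22), Golgi traffic (5 and 5 of 22, 5 and 6 adjusted over the list alone, adjusted p = 0.77) and the respiratory chain (5 and 1 of 37, adjusted p = 0.14). Neuronal genes (2 higher of 9, adjusted p = 0.71) had a median of -0.04 and a mean of 0.05, and endothelial markers (2 of 6 lower, adjusted p = 0.62) a median of 0.24 and a mean of -0.04. Airway markers were higher for 2 and lower for 1 of 6 (adjusted p = 0.73). Fibroblast markers had 4 tested members, 2 of them lower, and leukocyte markers 2, 1 of them lower, too few for a list test.

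Gene models that contain satellite repeats (Gm10800, Gm10801, Gm10717, Gm10722 and Gm21738, outside the naming rule and chosen after their values were seen) summed to 6031, 4097 and 4908 CPM in vector and 9338, 5740 and 16530 in deficient, but 312, 62.6 and 128 in WT and 47.9, 95.5 and 22.3 in mimetic. The lowest vector library was 42.9 times the highest mimetic one in CPM, from which library size is already divided out. TMM factors ran only from 0.97 to 1.03 over the libraries, which argues against scaling as the source of a ratio of that size. The share of Gm10800 in the sum ranged over 4.1 percentage points, a fixed proportion as reads of 1 repeat family counted under 5 models would give, so the genes are not separate observations. Genomic DNA stays open: genes at the lowest counts differed by -0.09 (median log2, vector minus mimetic; 95% bootstrap interval -0.16 to -0.04) but by 0.49 for deficient minus WT (0.44 to 0.55), and within lines their correlation with the satellite sum was 0.3 (permutation p = 0.23), so it cannot be told apart from a line effect. The Zeb1 form and the line are confounded here.

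Median fold changes of whole chromosomes shifted between lines, with chromosome 5 at 0.28 in deficient and 0.30 in mimetic against vector (log2, 9686 genes of at least 5 CPM), chromosome 18 at -0.25, -0.24 and -0.26 in WT, deficient and mimetic, and chromosome 14 at 0.27 in mimetic and 0.28 in deficient against WT. Uneven placement of changed genes by chance is argued against, since 0 of 200 shuffles of gene positions in each comparison reached the largest median. GC content and transcript length did not account for it, since 28 of 28 shifts of at least 0.15 kept over 50% of their size after regression on both. In 25 of the 28, both parts of the chromosome, split at the median gene, shifted the same way beyond 95% of 1000 random gene sets, but these were selected on the whole chromosome at a bound of 0.15 set after the medians were seen, which favours parts that agree; of 47 chromosomes and comparisons with either part at the bound, both parts reached it in the same direction in 23 and had opposite signs in 9. The comparisons share 4 lines and are not independent, DNA was not analysed here, and differences in copy number of whole chromosomes or parts of them and regional regulation stay open.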
